A study of Mus musculus with 6 samples.

How the data were processed

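Gene expression was measured in 6 primary cultures of mouse cerebral cortex, prepared from C57/B6 embryos at embryonic day 16 and kept in Neurobasal medium with B27 plus. Per the labels, 3 cultures were controls and 3 were exposed to terahertz radiation at 3.1 THz, an electromagnetic band between microwaves and infrared light, for 3 hours a day from day 5 to day 9 in vitro. RNA was collected at day 12 in vitro, and 0.2 µg of each sample was labelled with Cy3. Each sample was hybridised to its own 1-colour Agilent oligonucleotide array, so 6 arrays were analysed. The labels number the samples 1 to 3 in each group and do not say whether these came from separate dissections. The p-values therefore measure the spread between these samples, which may be partly technical.

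The scanner files hold spot intensity values that the authors deposited as written by Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes and the file headers. Per the file headers, the processed signal is a linear intensity with the background subtracted and spatial trends removed within an array, and it is not normalised between arrays. The fit value of the multiplicative trend was 0 on control 1 and between 0.013 and 0.038 on the other 5 arrays. That step may therefore not have been applied to control 1. The authors also deposited a table of log2 values. From its values, this table is on the log2 scale, is quantile normalised between arrays, is not centred per gene, and runs in the same direction as the scanner signal; the tool that made it is not given in the sources used here. Its column medians were 5.91 in all 6 samples, and its rank correlation with the scanner signal was 0.997 for control 1 and rounded to 1 for each of the other 5 arrays. All 6 arrays lay on 1 slide and were read in 1 scan, so slide and scan could not be tested as a batch. The controls occupied row 1, columns 1 to 3, while irradiated 1 lay in row 1, column 4, and irradiated 2 and 3 in row 2, columns 1 and 2. Row and column on the slide therefore overlap in part with group, and position was not tested.

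For the main analysis, the processed signal was taken to log2, spots marked as outliers by the scanner software were left out, spots of the same probe were averaged, and each array's 75th percentile over the probes that are not controls was subtracted. Of 56605 such probes, 10 had no unmarked spot on at least 1 array and were left out. A probe was kept if the scanner software called it well above background on at least 3 of the 6 arrays, counted without regard to group, which left 40552 probes. Probes were named through a table of mouse reference genes: 32994 by accession, 10224 by symbol and 520 by synonym, while 12867 kept the name in the file. Where a gene had several probes, the probe with the highest mean over the 6 arrays stood for it. This gave 26120 genes, of which 16266 have a name that is not a predicted gene, a Riken clone or an accession. Positions are those of the probe on mouse build mm9, per the file headers; no annotation of exons or untranslated regions in that build was used.

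Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as irradiated minus control over all 6 arrays without covariates. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. An uncorrected count, at unadjusted p under 0.05 and at least 1.5-fold, was kept beside it. Before the data were examined, 38 gene lists were fixed, covering synapses, channels, neuronal activity, oligodendrocytes, other cells that a cortical culture could hold, stress responses and metabolism. Their 805 genes include 802 on the array, and 37 lists had at least 5 measured genes. These were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes, again with an estimated correlation, and by fry, which tests whether a list's genes moved on balance one way and does not compare it with other genes. Adjustment was over the 37 lists. The genes named in the text follow a rule fixed at the same time. If fewer than 10 genes passed the adjusted threshold, the 10 higher and 10 lower named genes with the smallest unadjusted p were to be given as values. To these were added 4 members of each list called by camera, 2 members of each synaptic and oligodendrocyte list of the series title, and Gria1, Grin1, Dlg4, Syp, Neurod2, Mbp, Sox10 and Pdgfra. Some genes that this rule selects are not reported here. Other genes are named only as examples of a list and were chosen after their values were seen. A gene that was not well above background on any array of a group has only a bound there, computed against the higher of its own signal and the lowest signal well above background on each array.

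The numbers 1 to 3 are shared by the groups, and it was checked whether same-numbered arrays deviate together from their group means. The correlations of these deviations across genes were 0.53 for the number 1, 0.42 for the number 2 and 0.22 for the number 3. Each is over 0.1, the minimum set beforehand for taking the numbers as pairs. This pairing comes from the data and not from a statement in the labels. It was used in fits with the number as a block, which were run as alternatives. The p-values and intervals of the main analysis ignore it. Not every array correlated best with its own number, as control 3 reached 0.33 with irradiated 2. Control 2 reached 0.17 with irradiated 3, so the swapped pairing of the numbers 2 and 3 also passes the minimum. The 3 deviations of a gene in a group cancel out, so agreement at the number 1 by itself tends to raise these correlations. The check therefore speaks for a shared number 1 and does not settle the pairing of 2 and 3. With the replicate number as a block, 2036 genes met the uncorrected threshold, against 2186 without it.

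Alternatives tried were quantile normalisation, a normexp background correction with an offset of 50, both together, the authors' deposited log2 table, no filter on dim probes, a filter requiring all 6 arrays, the mean of all probes of a gene, every kept probe tested by itself, camera on ranks, an intensity trend in the variance, array quality weights, and each array left out in turn. The steps were tested on simulated data with the real gene means and spreads. In a simulated comparison of 26120 genes, 50 of 100 genes changed 4-fold and 0 of 100 genes changed 2-fold were called, and 1 unchanged gene was called. With the number as a block, 0 of the 100 genes changed 4-fold and 0 of the 100 changed 2-fold were called. These simulated arrays carry no pairing, so what the blocked fit can find on the real arrays is not known. An adjusted count of 0 from it is not read as absence of change. The number of arrays limits the precision: the median standard error of a log2 difference was 0.27. Files were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.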

Results

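The arrays recorded expression in cortical cultures 3 days after the last of the daily terahertz sessions, with 3 control and 3 irradiated cultures. The 75th percentile of the processed signal was 476, 687 and 1048 on control arrays 1 to 3 and 1225, 1291 and 921 on irradiated arrays 1 to 3. The share of spots well above background ranged from 64.9% on control 1 to 74.7% on irradiated 1. No spot was saturated. The slope of the spike-in controls was marked in range on control 1 and irradiated 2. It was marked out of range on control 2, control 3, irradiated 1 and irradiated 3. The first principal component, the axis along which the arrays varied most, held 54.5% of the variation. Control 1 stood at -114 on this axis, apart from the other arrays, which lay between -3.89 and 47.5. Markers of neurons, astrocytes, oligodendrocytes and microglia were all measured. Expression is given below as log2 signal relative to the array's 75th percentile, and differences as irradiated minus control on the log2 scale.

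The comparison of irradiated with control cultures asks whether exposure altered the expression of synaptic, oligodendrocyte or other genes. None of the 26120 genes passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.503. Other settings of limma also gave 0 genes, except quantile normalisation and the deposited log2 table with 2 each, and array quality weights with 9717, a fit that did not converge and rested mainly on 1 array per group. At unadjusted p under 0.05, 2395 genes were found, or 9.17%, where chance gives 1306. Of these, 2186 differed at least 1.5-fold, with 592 higher and 1594 lower in irradiated cultures. With control 2 left out the balance of that uncorrected count turned, to 1423 higher and 762 lower, and with control 3 left out it held 4305 genes. The 3 irradiated values lay all above or all below the 3 controls for 16.0% of genes, against 10% by chance if the 6 arrays were exchangeable, which shared replicate numbers make doubtful. The median difference over all genes was -0.13, and it was -0.05 after quantile normalisation.

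None of the synaptic genes fixed beforehand passed the adjusted threshold. Gria1, a subunit of AMPA receptors, measured 5.46 ± 0.02 in controls and 5.17 ± 0.30 in irradiated cultures (SD, n = 3 each), a difference of -0.29 with a 95% interval from -0.80 to 0.22. Grin1, the obligatory NMDA receptor subunit, differed by -0.61 (95% interval -1.41 to 0.19). Dlg4, which encodes the postsynaptic scaffold PSD-95, measured 2.86 ± 0.34 in controls and 2.32 ± 0.08 in irradiated cultures, a difference of -0.54 with an interval from -1.08 to 0.0014. All 3 irradiated values of Dlg4 lay below the controls, and its adjusted p was 0.503. Syp, encoding the vesicle protein synaptophysin, differed by -0.65 (interval -1.37 to 0.07). Neurod2, a transcription factor of cortical excitatory neurons, differed by -0.24 (interval -1.18 to 0.71). Probes of one gene disagreed in sign for Gria1, whose second probe differed by 0.60, for Grin1, whose 3 probes ranged from -0.61 to 0.76, and for Dlg4, whose 3 probes ranged from -0.54 to 0.0099. With the mean of its probes Dlg4 differed by -0.27.

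**Figure D1:**
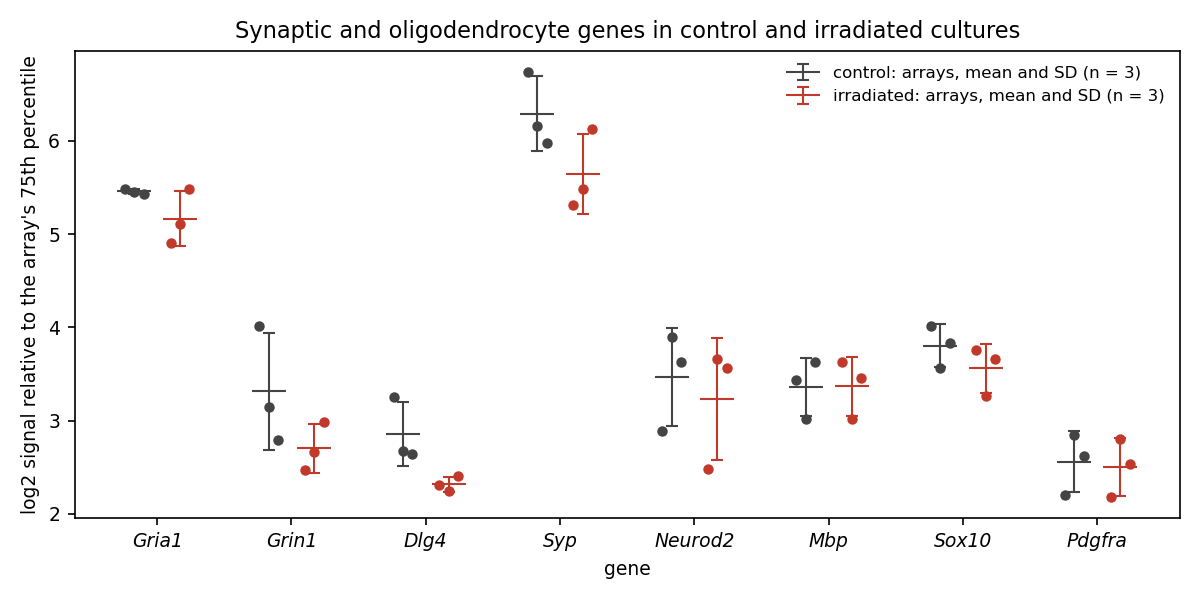
Log2 signal relative to the array's 75th percentile (vertical axis) for 8 genes of synapses, cortical neurons and oligodendrocytes (horizontal axis); each point is 1 array, placed from left to right by its number 1 to 3, and bars give the mean and SD (n = 3). The control and irradiated points overlap for each gene except Dlg4, where the irradiated mean was 2.32 and the control mean 2.86.

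As groups, the synaptic lists gave no call. Of 14 measured subunits of AMPA, NMDA and kainate receptors, 0 passed the adjusted threshold over all genes, and 0 when adjusted over the list alone. The list lay -0.05 from the mean of all other genes (camera adjusted p 0.915). Its members with the smallest unadjusted p were the kainate receptor genes Grik5, at -0.47, and Grik1, at -0.65. None of 28 measured genes of the excitatory postsynaptic density passed either adjustment; Dlg4 and Cnih2, an auxiliary protein of AMPA receptors at -0.61, had the smallest p. That list lay -0.03 from the other genes (camera adjusted p 0.910). None of 33 measured genes of presynaptic vesicles and active zones passed either adjustment. Their list lay 0.02 from the other genes (camera adjusted p 0.910), although its mean and median differences were -0.08 and -0.11. Its first members were Syngr1, a synaptic vesicle protein, at 0.61, and Syp, at -0.65. Of the 5 probes of Grik1, 3 were higher and 2 lower, from -0.65 to 0.15. The 2 probes of Cnih2 differed by -0.61 and 0.44, and those of Syngr1 by -0.41 and 0.61. The receptor and postsynaptic lists stood on the other side of 0 after quantile normalisation, at 0.0031 and 0.05, and the presynaptic list then lay at 0.16 (camera adjusted p 0.443).

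No oligodendrocyte gene passed the adjusted threshold either. Mbp, encoding myelin basic protein, measured 3.36 ± 0.31 in controls and 3.37 ± 0.32 in irradiated cultures, a difference of 0.01 with a 95% interval from -0.60 to 0.62. Sox10, a transcription factor of the oligodendrocyte lineage, differed by -0.24 (interval -0.78 to 0.29). Pdgfra, the growth factor receptor of oligodendrocyte precursors, differed by -0.05 (interval -0.66 to 0.56), and by 0.08 after quantile normalisation. The 3 probes of Mbp were all above 0, from 0.0083 to 0.63, and the 3 probes of Pdgfra all below 0, from -0.47 to -0.05. Of 21 measured genes of myelinating oligodendrocytes, 0 passed over all genes and 0 when adjusted over the list alone, and the list lay 0.03 from the other genes (camera adjusted p 0.703). The list's mean and median differences were -0.08 and -0.13, below 0, while the test compares it with other genes, whose mean also lay below 0, and put it higher. Myrf, the transcription factor that drives myelin genes, differed by 0.58 (standard error 0.23), with all 3 irradiated values above the controls and an adjusted p of 0.503. Gal3st1, an enzyme of sulfatide synthesis, differed by -0.53. Of 16 measured genes of oligodendrocyte precursors, 0 passed either adjustment, and the list lay -0.077 from the other genes (camera adjusted p 0.910). With the replicate number as a block, camera did not call it either (-0.077, adjusted p 0.761; 0.942 with an estimated correlation). Fry tests a list against no change, not against other genes. The list's own mean difference was -0.18, where the mean of all genes was -0.11, and fry gave an adjusted p of 0.705 without the block and 0.031 with it. Cspg4, a member encoding the NG2 proteoglycan, differed by -0.52 (standard error 0.35), and its 3 probes ranged from -0.52 to 0.039.

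Some myelin genes varied between cultures of the same group by more than they differed between groups. Mobp, a myelin structural gene, measured 1.86 on control 1 and 1.86 on irradiated 1, and lay below the lowest signal well above background on control 2 and irradiated 2. Mag, encoding myelin-associated glycoprotein, measured 3.99 and 3.08 on the arrays numbered 1, against values from -0.91 to 0.49 on the others. Relative to all genes and to the mean of the 6 arrays, the myelinating list stood at 1.02 on control 1 and 1.07 on irradiated 1, and at -0.95 on control 2 and -0.77 on irradiated 2. The list passed camera with control 1 left out (0.55 above the other genes, adjusted p 0.0031) and with irradiated 2 left out (0.42, adjusted p 0.031). With irradiated 1 left out it lay at -0.50, so which arrays were compared set its direction.

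Markers of microglia and macrophages showed the same structure at a larger scale. Their list stood at 1.38 on control 1 and 1.68 on irradiated 1, at -0.66 and -0.41 on the arrays numbered 2, and at -1.09 and -0.91 on those numbered 3. Of 19 measured genes, 0 passed the adjusted threshold and 0 when adjusted over the list alone, and the list lay 0.24 above the other genes (camera adjusted p 0.421). With the replicate number as a block, the list passed camera (0.24, adjusted p 0.0069), and 3 lists were called in all. That call was lost with an estimated correlation (unadjusted p 0.0722; the smallest adjusted p of any list was then 0.942). With one array left out, the list lay at 0.999 without control 1 (adjusted p 2.9e-06), 0.76 without irradiated 3 (0.0070) and 0.51 without irradiated 2 (0.031), which passed camera. It lay at -0.023 without control 2, -0.24 without control 3 and -0.54 without irradiated 1, which did not. With both arrays numbered 1 left out it lay at 0.22 and passed (adjusted p 0.014).

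**Figure D2:**
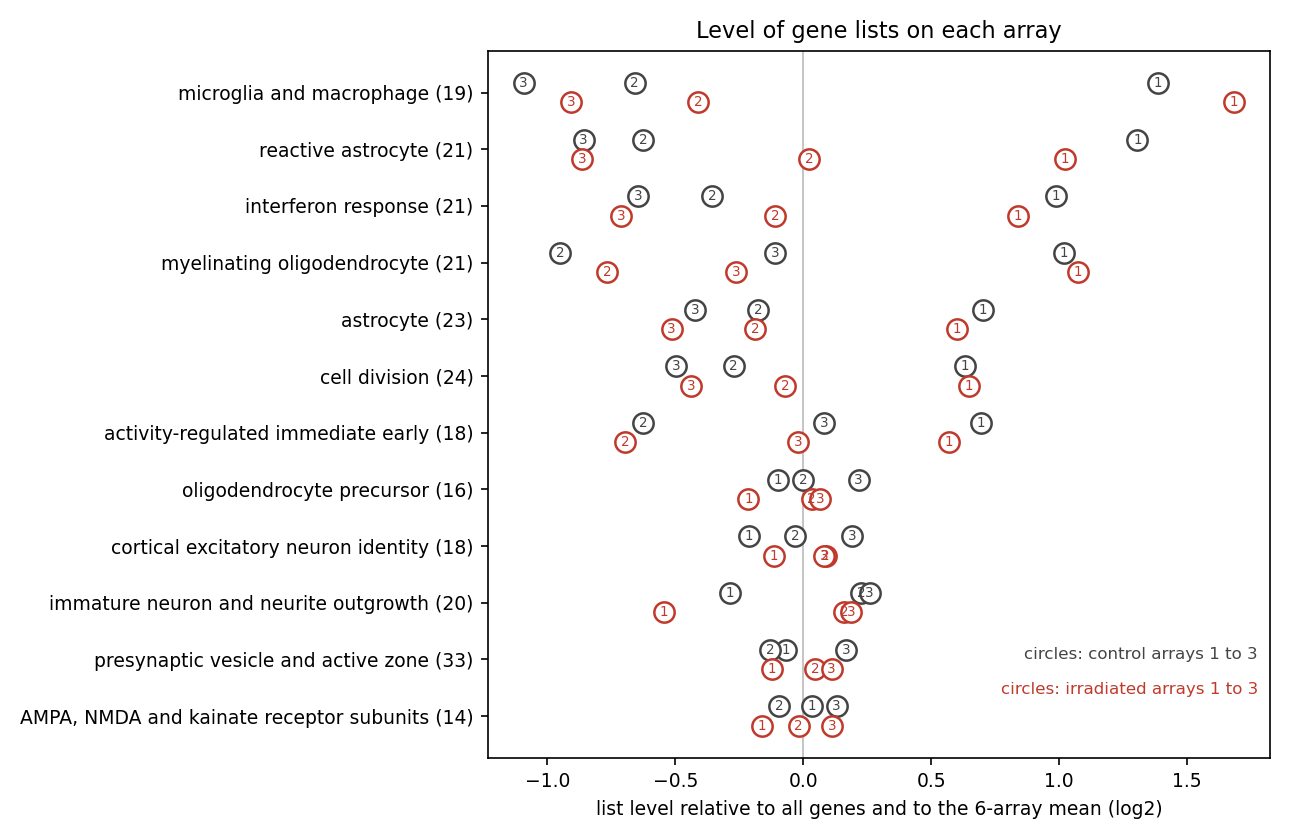
Mean level of 12 gene lists on each array, relative to all genes and to the mean of the 6 arrays (horizontal axis, log2); grey circles are control arrays, red circles irradiated arrays, the digit in a circle is the array's number, and the number of measured genes follows each list's name. The microglial list stands at 1.38 on control 1 and 1.68 on irradiated 1, while the receptor and presynaptic lists stay between -0.16 and 0.17 on all 6 arrays.

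Other lists followed the array number in a like manner. The reactive astrocyte list stood at 1.31 on control 1 and 1.02 on irradiated 1, the interferon list at 0.99 and 0.84, and the general astrocyte list at 0.70 and 0.60. Cell division genes stood at 0.63 and 0.65 on these arrays. The list of immature neurons and neurite outgrowth stood at -0.29 and -0.54. Immediate early genes, which respond to neuronal firing, stood at 0.69 and 0.57 on the arrays numbered 1 and at -0.63 and -0.70 on those numbered 2. Among them, Nr4a1 measured 4.27 and 3.82, then 1.46 and 1.44, and 2.79 and 2.74 on control and irradiated arrays 1, 2 and 3. None of these lists passed camera between irradiated and control cultures in the analysis reported. The reactive astrocyte list passed camera, higher, with array quality weights (adjusted p 0.0046) and with both arrays numbered 1 left out (adjusted p 0.019). It also passed, higher, without control 1 (adjusted p 2.9e-06) and without irradiated 3 (adjusted p 0.018). With control 1 left out, 10 lists were called, and 8 with irradiated 3 left out, 5 with irradiated 2 left out and 4 with irradiated 1 left out.

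Camera called 2 lists, both lower in irradiated cultures. Genes of cytosolic ribosomal proteins lay -0.27 from the other genes (adjusted p 0.00013), with differences below 0 in 29 of 30 measured members. Genes of oxidative phosphorylation lay -0.24 from the other genes (adjusted p 0.00069), with differences below 0 in all 27 measured members. Neither call held with an estimated correlation (adjusted p 0.961 for both). Fry, which tests against no change and not against other genes, called no list (smallest adjusted p 0.335). After quantile normalisation the ribosomal list lay 0.07 above the other genes (adjusted p 0.542) and the oxidative phosphorylation list 0.07 above them (adjusted p 0.663). No member passed the adjusted threshold over all genes or when adjusted over the list alone. Among ribosomal members, Rpl13 differed by -0.53 and Rpl18 by -0.54, each with a standard error of 0.23. The members of the respiratory chain with the smallest unadjusted p were Cox6a1, at -0.56 (0.016 after quantile normalisation), Ndufb8, at -0.45, Cox4i1, at -0.60, and Cox7a2, at -0.54. The 4 probes of Rpl13 ranged from -0.54 to 0.66, and the 2 probes of Ndufb8 from -0.45 to 0.16.

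**Figure D3:**
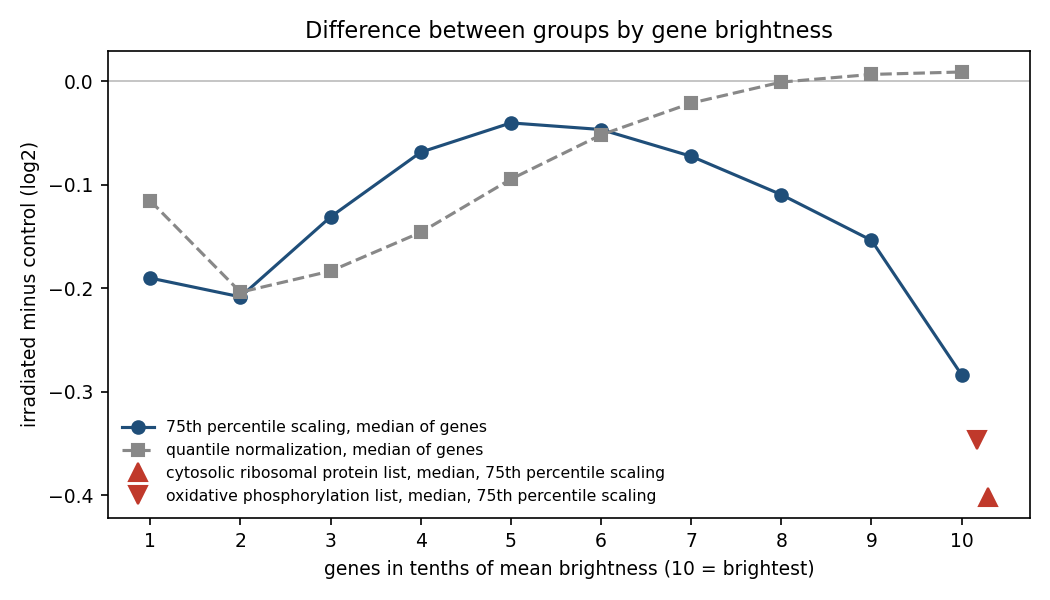
Median difference between irradiated and control cultures (vertical axis, log2) for genes in 10 equal groups of mean brightness (horizontal axis), with 75th percentile scaling (blue) and quantile normalisation (grey); red triangles give the medians of the 2 called lists at their mean brightness rank. With 75th percentile scaling the medians were -0.19 and -0.21 in the 2 dimmest groups, -0.04 in group 5 and -0.28 in the brightest group, and with quantile normalisation the brightest group had a median of 0.0090.

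Camera called none of the other lists in the analysis reported, with the preset correlation and 75th percentile scaling. They include the heat shock, unfolded protein, oxidative stress, DNA damage and apoptosis lists. In none of the 37 lists did a member pass when adjusted over the list alone. Of the 35 lists that camera did not call, the smallest adjusted p was 0.375.

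The named genes with the smallest unadjusted p were mostly dim and are given as values, each with an adjusted p of 0.503. Lower in irradiated cultures were the olfactory receptor genes Olfr786 (-1.01), Olfr1280 (-0.93), Olfr338 (-1.28) and Olfr1022 (-1.31). Olfr1375 (-1.21), which the array's annotation describes as an olfactory receptor pseudogene, was lower too. So were Dsc1, a desmosomal cadherin (-1.06), Sytl3 (-0.92), Cmtm2b (-1.50) and the non-coding RNA Platr5 (-1.20). Krtap26-1, a hair keratin-associated gene on chromosome 16 (88647329 to 88647388), was not well above background on any irradiated array and was at least 1.83-fold lower there. Olfr338 and Olfr1022 were well above background on only 1 irradiated array each. The 3 kept probes of Sytl3 ranged from -0.92 to 0.30.

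Higher in irradiated cultures were Lncpint, a long non-coding RNA induced by p53 (1.16, standard error 0.25), and Ipw, an imprinted non-coding RNA of the Prader-Willi region on chromosome 7 (66931735 to 66931794). Ipw measured 0.82 ± 0.55 in controls and 2.22 ± 0.50 in irradiated cultures (SD, n = 3 each), and was 2.63-fold higher. Htr1b, encoding the serotonin receptor 1B, differed by 1.04, Serac1 by 0.90, Acrbp by 1.08 and the vomeronasal receptor gene Vmn2r86 by 1.06. Adamts6, a secreted metalloprotease, was not well above background in controls and was at least 1.12-fold higher. Vmn2r42, Spag6 and Hectd2os were not well above background in any control, and the bound gave no fold. With normexp background correction, Vmn2r42, Htr1b, Spag6, Adamts6, Hectd2os and Vmn2r86 lay below 0.

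The positions of the main probes on build mm9 were chromosome 11, 57141228 to 57141287, for Gria1, chromosome 2, 25146927 to 25146986, for Grin1, and chromosome 11, 69858757 to 69858816, for Dlg4. They were chromosome X, 7230297 to 7230356, for Syp, chromosome 18, 82727929 to 82727988, for Mbp, and chromosome 15, 78985343 to 78985402, for Sox10. Pdgfra was read at chromosome 5, 75593888 to 75593947, and Neurod2 at chromosome 11, 98187943 to 98188002.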

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

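The settings that left out both arrays numbered 1, those that combined the replicate block with quantile normalisation, an estimated correlation or fry, and the choice of which lists are given here with a shift followed after results were seen. The count of genes past the adjusted threshold was 0 as reported and in each alternative run, except for 2 with quantile normalisation, 2 with the authors' deposited log2 table and 9717 with array quality weights. The 2 genes after quantile normalisation, named after their values were seen, were the predicted gene Gm20783 (2.52, adjusted p 0.045) and the transcript AK045452 (2.22, adjusted p 0.045); with the replicate block added, quantile normalisation called 0 genes (smallest adjusted p 0.489) and 2015 met the uncorrected threshold. The weights were 6.68 for control 2, 6.36 for irradiated 2 and between 0.18 and 0.60 for the other 4 arrays, and their estimation did not converge, so this count rests mainly on 1 array per group; 39 of the 44 named genes passed under it. The uncorrected count of 2186 became 3300 with normexp correction (241 higher, 3059 lower), 793 with normexp and quantile normalisation (272 higher, 521 lower), 3737 without the filter on dim probes, 5398 with array weights and 954 without both arrays numbered 1. With one array left out it ranged from 739, without irradiated 2, to 4305, without control 3; it was 1198 without control 1, 843 without irradiated 1, and 2185 without control 2, where 1423 were higher and 762 lower. The share of lower genes was 72.9% as reported, 92.7% with normexp correction and 34.9% without control 2; the median of all genes was -0.22 with normexp correction, against -0.13. The cause of these differences was not tested, except where the weights show it.

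The number of lists called, 2 as reported, was 0 with an estimated correlation, with or without the replicate block, with fry, with quantile normalisation, with normexp and quantile normalisation, with the deposited table and without the dim filter. It was 1 with the mean of all probes (ribosomal) and with quantile normalisation under the block (microglia, higher, adjusted p 0.033). It was 4 with array weights, which added potassium channels and reactive astrocytes, and 4 without both arrays numbered 1, which added microglia and reactive astrocytes. With normexp correction it was 3, all higher and none of them the reported ones: sodium and calcium channels, potassium channels, and microglia. With one array left out it ranged from 2 to 10, and lists of astrocytes, cell division, interferon, inflammation, immature and mature neurons, glycolysis, myelin and ependyma were called in at least 1 of these runs. With the replicate number as a block, 2036 genes met the uncorrected threshold and 3 lists were called, microglia being added; with 75th percentile scaling the block changed no other camera or gene call. Fry, which tests against no change and not against other genes, called the precursor (adjusted p 0.031) and GABAergic (adjusted p 0.038) lists under the block. A slide block was not run, since all 6 arrays share 1 slide.

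List directions were unstable as a whole. Over 666 alternatives for the 37 tested lists, the direction turned in 177, of which 55 left out one array, and 33 lists turned at least once; 13 lists outside the reported 2 were called in at least 1 alternative. Shifts are given for 8 lists, those of the series title and those called by camera with or without the block, because listing each turn of all 37 was too long; the 29 others turned in 136 of 522 alternatives and are given no shift here. Of 784 alternatives for named genes, 722 kept the sign and stayed short of the threshold, 39 passed it, all with array weights, and 23 turned.

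With normexp correction, Vmn2r42 (-0.41), Htr1b (-0.048), Spag6 (-0.40), Adamts6 (-0.32), Hectd2os (-0.41), Vmn2r86 (-0.13), Pdgfra (0.011), and the receptor (0.0997), postsynaptic (0.12) and precursor (0.046) lists turned. With quantile normalisation, with or without the block, Cox6a1 (0.016), Pdgfra (0.079) and the receptor (0.0031), postsynaptic (0.051), oxidative phosphorylation (0.067) and ribosomal (0.0698) lists turned, as did the precursor list without the block (-0.030). With normexp and quantile normalisation, Cox6a1 (0.053), Pdgfra (0.082) and the receptor (-0.019), postsynaptic (0.043), precursor (-0.024), oxidative phosphorylation (0.054) and ribosomal (0.058) lists turned. With the deposited table, Cox6a1 (0.053), Pdgfra (0.0796) and the receptor (0.0033), postsynaptic (0.051), precursor (-0.0296), oxidative phosphorylation (0.069) and ribosomal (0.071) lists turned. Where a shift kept its sign, the direction of the test turned. With the mean of probes, Gria1 (0.16) and the receptor (0.15) and postsynaptic (0.093) lists turned; without the dim filter the receptor (0.067), postsynaptic (0.087) and precursor (0.036) lists; with array weights the receptor (0.060) and postsynaptic (0.085) lists; and without both arrays numbered 1 Mbp (-0.085) and the receptor list (0.029). With one array left out, Neurod2 ranged from -0.53 to 0.14, Pdgfra from -0.23 to 0.11, Mbp from -0.16 to 0.18, and the lists of receptors from -0.11 to 0.024, postsynaptic genes from -0.10 to 0.081, presynaptic genes from -0.038 to 0.11, precursors from -0.15 to 0.011, myelin from -0.50 to 0.55 and microglia from -0.54 to 0.999. For the myelin and microglial lists, whose levels differed by array number, leaving out 1 array left its number in only 1 group. Without both arrays numbered 1 these lists lay at 0.016 and 0.22. No cause was tested for the other turns and ranges. Signal over background limits the dim genes: control 1 had the lowest share of spots well above background, at 64.9%.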

Other observations

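The tests of neuron share, array brightness and scaling, the focus on the arrays numbered 1, the interval applied to both tests of the share of lower genes, and the removal of genes already seen from the second microglial list were chosen after the results were seen. Across genes, more differences at unadjusted p under 0.05 were found between array numbers than between treatments. In a limma fit with both group and number, 173 genes differed between numbers at an adjusted p of 0.05 and 4141 at unadjusted p under 0.05, while irradiated against control gave 0 and 2361. The same fit called 0 of 100 simulated genes changed 4-fold, but the simulated arrays carry no pairing. What this fit can find between treatments on the real arrays is therefore not known. That 0 is not read as absence of change, and the comparison rests on the unadjusted counts. The test between the 3 numbers has more degrees of freedom than that between the 2 groups, so the counts are not strictly alike. Pairing irradiated 2 with control 3 and irradiated 3 with control 2 gave 120 genes, and the 4 pairings that part the arrays numbered 1 gave 0 each; with the replicate number as a block, 2036 genes met the uncorrected threshold between treatments. Both arrays numbered 1 were the 2 highest of the 6 for 17 of 19 microglial genes, 21 of 24 cell division genes, 18 of 21 reactive astrocyte genes and 14 of 21 myelinating oligodendrocyte genes, against 13.1% of all genes. They were the 2 lowest for 12 of 20 genes of immature neurons and 8 of 16 precursor genes, against 18.4% of all genes.

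Within the oligodendrocyte lineage, precursor and myelin genes stood apart on these arrays. Gpr17, a receptor of newly committed oligodendrocytes, measured 5.39 on control 1 and 5.24 on irradiated 1 and between 6.43 and 6.63 on the other 4 arrays. Olig1, a transcription factor of the whole lineage, stayed between 4.33 and 4.88 on all 6 arrays. No group in the labels separates the numbers, so no biological explanation such as culture age or dissection was tested.

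Microglial genes were high on both arrays numbered 1. Other amounts of microglia in the cultures are a candidate explanation: of 23 measured genes in a second microglial list that shares none with the first, 87.0% had these 2 arrays as their highest, against 13.1% of all genes. With 3 more genes, which exploration had already shown among the extreme ones, the share was 84.6% of 26. The genes of 1 cell type move together and are not independent, so a second list would tend to follow the first whatever the cause. The share was also 87.5% for cell division genes and 85.7% for reactive astrocyte genes. The precursor list was lower on these 2 arrays than on the other 4, by -0.23, while the microglial list was higher by 2.30. This does not exclude a lower share of neurons, since precursors need not move with the other non-neuronal cells. Lists of astrocytes (0.98), myelinating oligodendrocytes (1.57) and endothelial cells and pericytes (0.76) were also higher there. That of radial glia and progenitors lay at -0.07, and that of immature neurons at -0.62. Other neuronal lists did not all go one way. Relative to all genes and to the 6-array mean, the mature neuron list stood at 0.12 on control 1 and -0.25 on irradiated 1. The cortical excitatory list stood at -0.21 and -0.11 there, and the presynaptic list at -0.07 and -0.12. These 2 arrays were the lowest for 9 of 18 cortical excitatory genes and 1 of 17 mature neuron genes. The lists thus do not settle the share of neurons. Array brightness does not separate the arrays numbered 1 from the rest, since the 75th percentile signal of irradiated 1 was 2.57 times that of control 1, among the brightest and the dimmest of the arrays. Why cultures with 1 number share this profile stays open.

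The ribosomal and oxidative phosphorylation lists were called lower in irradiated cultures. A difference between arrays that grows with brightness among the brighter genes may account for it. The median difference did not grow over the whole range: it was -0.19 in the dimmest of 10 brightness groups, -0.04 in group 5 and -0.28 in the brightest. Among 10000 random lists matched on brightness, the ribosomal median of -0.40 lay at the 41.6th percentile and the oxidative phosphorylation median of -0.35 at the 54.4th percentile. The medians of the random lists were -0.39 and -0.35. The random lists were drawn from all genes of like brightness, the genes of the 2 called lists included, which can draw the percentile towards the middle. An effect of irradiation on all bright transcripts would look the same and stays open as untested. Of the 10 splits of the 6 arrays into 3 and 3, the real one called 2 lists and the highest other 16, and 8 splits called at least 2; the 4 splits that keep the arrays numbered 1 together called 11 to 16 lists, several times the real count, which points to a structure of the samples. Control 1, control 3 and irradiated 3 against the rest, which parts these arrays, called 15. Among the splits that part all 3 pairs, the highest other called 2 lists, and with the replicate number as a block 2036 genes met the uncorrected threshold. With 10 splits no share under 0.05 can be reached.

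More genes were lower than higher in the uncorrected count. The 75th percentile scaling is not its whole source in the fit without a block, since 71.7% were lower after quantile normalisation too. With the replicate number as a block, 62.8% were lower after quantile normalisation, under the 65% set for this test, and 63.8% with 75th percentile scaling. Dim probes that read relatively higher on the dimmer control arrays may add to the excess of lower genes and are not settled. After quantile normalisation without the block, 69.0% of the 394 counted genes above the median brightness were lower, against 72.3% of the 1711 below it. A share over 65% among the brighter genes had been set beforehand as speaking against dim probes, and 69.0% is over it. The exact binomial 95% interval, from 64.2% to 73.6%, reaches below that bound, and the question was left open on this ground, a condition added after the value was seen. The interval takes genes as independent, which they are not. The real split gave 2186 genes and the highest other split 2074, from control 1, control 2 and irradiated 1 against the rest, and 1 of the 10 splits, the real one, gave as many. For genes past the adjusted threshold, all 10 splits gave 0. Neither share can fall under 0.05 with 10 splits.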
